A study of Mus musculus with 16 samples.

How the data were processed

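RNA was measured in CDH1-positive epithelial cells sorted by FACS from mammary glands of female mice aged 8 weeks. CDH1 is the epithelial adhesion protein E-cadherin. The labels describe total RNA extracted with Trizol, labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per sample. There were 16 samples in 4 groups of 4, and each sample's group was read from its own label. According to the genotype labels all 4 groups carried the MMTV-cre transgene, which drives recombination in mammary epithelium and also in some other secretory tissues. The groups were wild type, Pten WT/null (1 allele with loxP sites), Pten F341V (an allele with the F341V change and an allele with loxP sites) and Pten null (both alleles with loxP sites). The labels call the replicates biological without saying that each came from a separate animal, so p-values measure the spread between these samples. Most samples were of backcross generation 3 into FVB/N, and wild-type replicates 3 and 4 were of generation 4.

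The deposited values were used as given. They are log2 values that the authors made with RMA, per the submitters' processing notes, which give no version, and the quantile step of RMA had brought the arrays to nearly the same distribution. Sample medians lay between 5.14 and 5.22 log2. Arrays hold no read depth, and precision is limited by the number of arrays and, for dim and for the brightest genes, by background and the array's maximum. All 16 columns matched a sample, and no pair of samples was a copy, since the largest probe set difference between any 2 samples was never under 3.49 log2.

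Of 45101 probe sets, 35890 were listed in the annotation used, 34958 of them with 1 gene symbol and 932 with several. The 9211 unlisted probe sets, the 932 with several symbols and 64 control probe sets were left out, which left 34945 probe sets. Symbols were checked by Entrez number against the RefSeq gene table of assembly GRCm38.p6, of which 99.4% matched and 0 symbols changed, and that table was otherwise used only to find which genes neighbour each other. Each of 18193 genes was represented by its probe set with the highest mean over all arrays. Genes whose mean lay under the 25th percentile (4.30 log2) were left out, so that 13645 genes were tested. No probe set was named Pten in the annotation used, so the level of Pten was not analysed here and the genotype labels could not be checked through it.

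A linear model of the 4 group means was fitted to all 16 samples with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 12 residual and 2.65 prior degrees of freedom. The 6 pairwise differences were tested two-sided, and so was the difference of Pten WT/null from the midpoint of wild type and Pten null. Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. Errors are the SD between samples, or the SE of a difference from the fit. Tables were read with the data.table package, version 1.17.8. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 drew the plots.

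Gene lists, the named-gene rule, the comparisons and most alternatives were fixed before the data were examined. The 29 lists, with 473 entries, were pan-luminal epithelium, hormone-sensing luminal cells, luminal progenitors, basal and myoepithelial cells, milk and alveolar genes, fibroblasts, adipocytes, endothelium, macrophages and myeloid cells, T and NK cells, B and plasma cells, red blood cells, mitosis, DNA replication and E2F targets, FoxO targets, PI3K pathway components, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, ATF4 and amino acid supply, the unfolded protein response, cytosolic ribosomal proteins, oxidative phosphorylation, p53 targets, NF-kB and secreted inflammatory factors, the interferon response, MHC class II, immediate early and dissociation stress, and the circadian clock. Of the entries, 43 had no single-gene probe set and 416 were tested. Members were counted as risen, fallen or not passed over all genes tested, and again with p-values adjusted over the list alone. Each list with at least 3 tested members (28 of the 29) was compared with all other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the data, with adjustment over the lists of a comparison. The fry test was run beside it, which asks whether the members of a list move, on balance, 1 way.

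Named genes were, for each pairwise comparison, the 10 largest rises and the 10 largest falls among genes that passed and whose samples did not overlap between the groups, without genes known only by a clone or locus name. Where fewer than 5 genes passed, the 5 with the smallest p were named, and the midpoint comparison named the 5 with the smallest p. Up to 4 tested members with the smallest p could be named from each list. Genes named outside this rule are said to have been chosen after their values were seen.

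The similarity of the changes from wild type was measured across genes by Pearson's r and Spearman's rho. It was set against 100 simulated draws in which the changes shared only their control samples, and was computed again with the wild-type samples split between both changes. The number of genes that rose in both Pten F341V and Pten null was set against 100 draws in which Pten F341V had no change of its own. Every other way to divide the 8 samples of a pairwise comparison into groups of 4 was fitted, which gives 35 divisions, and 100 random regroupings were fitted for the midpoint comparison.

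The alternatives were no filter on dim genes, a filter at the 50th percentile, the mean of all probe sets of a gene, all single-gene probe sets tested, only the groups compared in the fit, eBayes with trend and robust settings, array weights, arrays centred on their medians, quantile normalization of the deposited values, the replicate number as a block, the backcross generation as a covariate, wild-type samples of generation 4 left out, and each replicate left out in turn. After the data had been seen, scaling to 9 hybridisation spike-in probe sets was added, and so was leaving out Pten WT/null replicates 1 and 4 together, or Pten null replicates 1 and 2 together. The fit was tested on simulated data with each gene's own mean and residual SD and independent normal noise. Of 100 genes among 13645 given a change of 1 log2, between 74% and 82% were recovered per comparison, and of 100 given a change of 2 log2, between 90% and 97%. False calls made up 2.76% to 7.37% of the calls. A simulated shift of 0.5 log2 in the mitosis list was found by camera, with 0 other lists of 28 called.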

Results

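Gene expression was profiled on arrays in CDH1-positive mammary epithelial cells from 4 wild-type, 4 Pten WT/null, 4 Pten F341V and 4 Pten null samples. Pten encodes the phosphatase that opposes PI3K signalling. Values are log2 RMA values, and the array medians ranged from 5.14 in Pten WT/null replicate 1 to 5.22 in Pten null replicate 4. Epithelial transcripts were abundant in every group, with Epcam, an epithelial adhesion molecule, at 11.08 ± 0.99 in wild type and 11.69 ± 0.37 in Pten null (SD, n = 4), and Cdh1 at 10.48 ± 0.71 and 10.25 ± 0.34. Ptprc, which marks blood-derived cells, was also high, at 11.67 ± 0.53 in wild type and 11.63 ± 0.30 in Pten null. These 3 genes were picked after their values had been seen. Markers of macrophages and myeloid cells averaged 11.62 log2 in wild type, 11.65 in Pten WT/null, 11.71 in Pten F341V and 11.63 in Pten null. Blood-derived cells were thus likely present. Differences in any comparison may come in part from the cell mix, which was not measured.

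The Pten null samples stood apart from the other 12 along the first principal component, which held 49.1% of the variance, while the second (16.5%) spread samples within groups, with Pten WT/null replicate 1 at its upper end. Correlations between samples ranged from 0.931 to 0.990 within groups, the lowest in Pten WT/null, and from 0.858 to 0.985 between groups. The 20 brightest probe sets held 4.54% ± 0.21 of the signal in Pten null and 3.77% ± 0.12 in wild type (SD, n = 4, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 samples allow). Hybridisation spike-in controls averaged 10.73 ± 0.23 log2 in Pten null and 10.23 ± 0.15 in wild type (n = 4, exact permutation p = 0.0286). Scaling to them lowers every gene of Pten null by 0.50 log2 against wild type, and takes the median difference of all genes from -0.11 to -0.61. Changes in Pten null are therefore relative to these medians, and directions that turn with the scaling are given beside each group of genes.

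**Figure D1:**
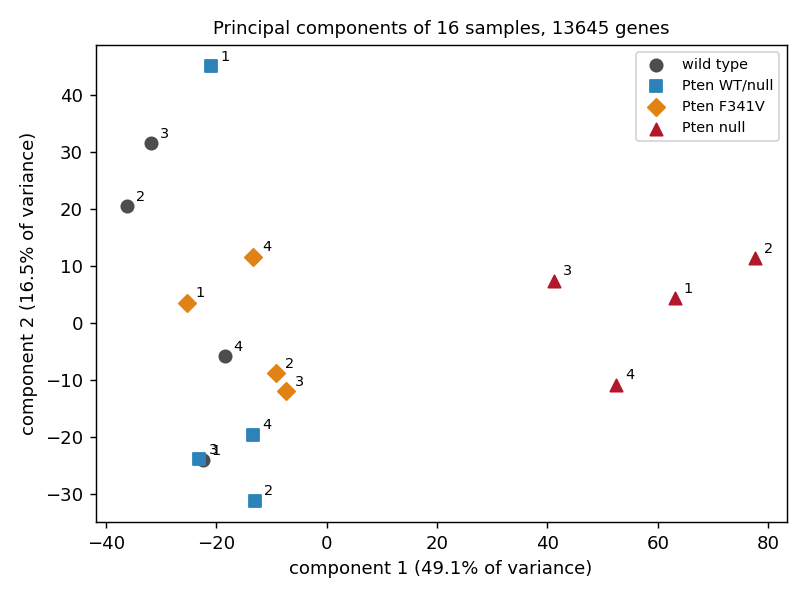
Each point is a sample placed by its scores on the first (horizontal, 49.1% of the variance) and second (vertical, 16.5%) principal components of 13645 genes, with symbols for the 4 groups and replicate numbers beside them. The 4 Pten null samples lie to the right of all 12 others, and Pten WT/null replicate 1 lies highest.

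**Figure D2:**
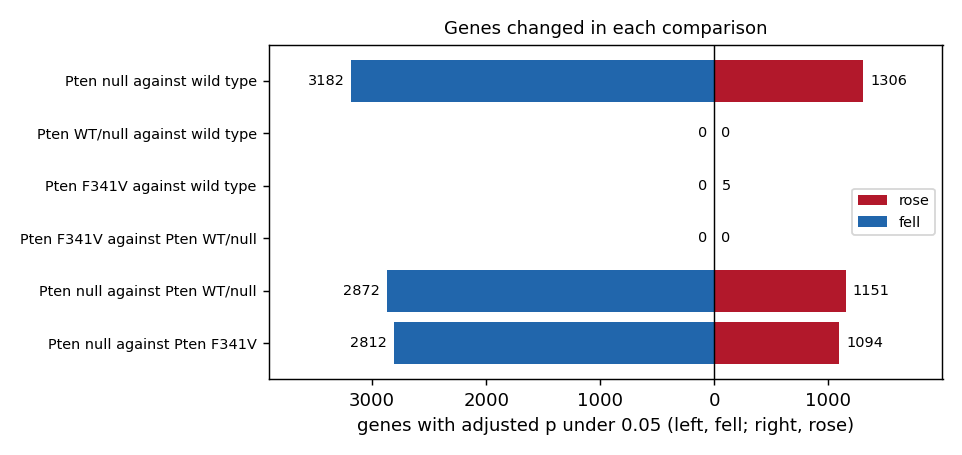
Bars give the number of genes with adjusted p under 0.05 in each of the 6 pairwise comparisons, those that fell to the left and those that rose to the right, of 13645 tested. The 3 comparisons with Pten null have 4488, 4023 and 3906 changed genes and the other 3 have 0, 5 and 0; with scaling to the spike-in controls the 3 counts with Pten null become 9096, 8995 and 7431, nearly all of them falls.

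The comparison of Pten null with wild type asks what loss of both Pten alleles changed in these cells. The largest rises were in genes for secreted proteins of saliva and glandular fluid. Bpifa2, the parotid secretory protein, stood at 14.45 ± 0.02 log2 in Pten null and 2.59 ± 0.12 in wild type (SD, n = 4, adjusted p = 1.11e-19). Cst10, a cystatin, rose by 11.60 log2, Pip, the secreted prolactin-induced protein, by 11.29, Amy1, salivary amylase, by 11.29, and Dnase1, a secreted DNase, by 11.10. Smr3a (11.04), Prpmp5 (10.52), the chitinase gene Chia1 (10.29), Dcpp1 (9.39) and Car6, the carbonic anhydrase of saliva (9.29), rose as well. All 4 Pten null samples lay above all 4 wild-type samples for each of these genes, and Bpifa2, Cst10, Dnase1 and Chia1 averaged from 14.45 to 14.64 log2 in Pten null, where the brightest probe set of any sample read 14.70. All but Car6 averaged under the filter level of 4.30 log2 in wild type, and Car6 read under it in 2 of the 4 samples. Differences are compressed near background and near the array's maximum, so the sizes say little beyond a large rise, and their order carries no meaning. Among the falls was Serpinb11, a serpin (4.09 ± 0.48 against 9.30 ± 1.11 log2, n = 4, adjusted p = 0.000203). The matrix genes Vcan, a proteoglycan (-4.12), and Adamts20, a protease (-4.01), fell, as did the genes of Wnt signalling Wif1, a secreted inhibitor (-4.02), Sostdc1, an antagonist of BMP and Wnt (-3.92), and Rspo1, which strengthens the signal (-3.87). Falls were also seen in the chemokine receptor gene Ccr1 (-3.91), in Moxd1 (-3.85) and in Tenm2 (-3.79). Nupl1, a nucleoporin gene, fell by 3.98 on its brightest probe set, while its other probe sets gave -0.44, -0.34 and -0.27 log2, the last with an adjusted p of 0.306. Dim further probe sets of Vcan (-0.14 to 0.36) and Tenm2 (0.18 and 0.32) did not follow the bright ones either. With Pten null replicates 1 and 2 both left out, Rspo1 no longer passed (log2 difference -3.61, adjusted p = 0.0884). Serpinb11, Adamts20 and Rspo1 averaged under 4.30 log2 in Pten null, so the sizes of their falls are uncertain.

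A list of 21 salivary secretory genes, written down only after these genes had been seen, had 19 tested members in this comparison, of which 18 rose and 1, Smr2, fell (-0.46 log2). Their median difference of 8.37 log2 has the same limits at background and at the array's maximum. The list averaged 10.86 ± 0.23 log2 in Pten null, 3.67 ± 0.12 in wild type, 3.79 ± 0.15 in Pten WT/null and 3.86 ± 0.13 in Pten F341V (SD, n = 4). Picked from it after their values were seen were Bhlha15, a transcription factor of secretory acinar cells (10.05 ± 0.86 against 4.79 ± 0.16), Pitx1, a transcription factor of oral epithelium (7.04 ± 0.54 against 4.28 ± 0.12), Egf (8.51 or above in every Pten null sample against 3.49 ± 0.23) and Lpo, the lactoperoxidase gene (12.03 ± 0.92 against 4.15 ± 0.34). Mucl2 and Xist were added to the plots of single genes after their values were seen.

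**Figure D3:**
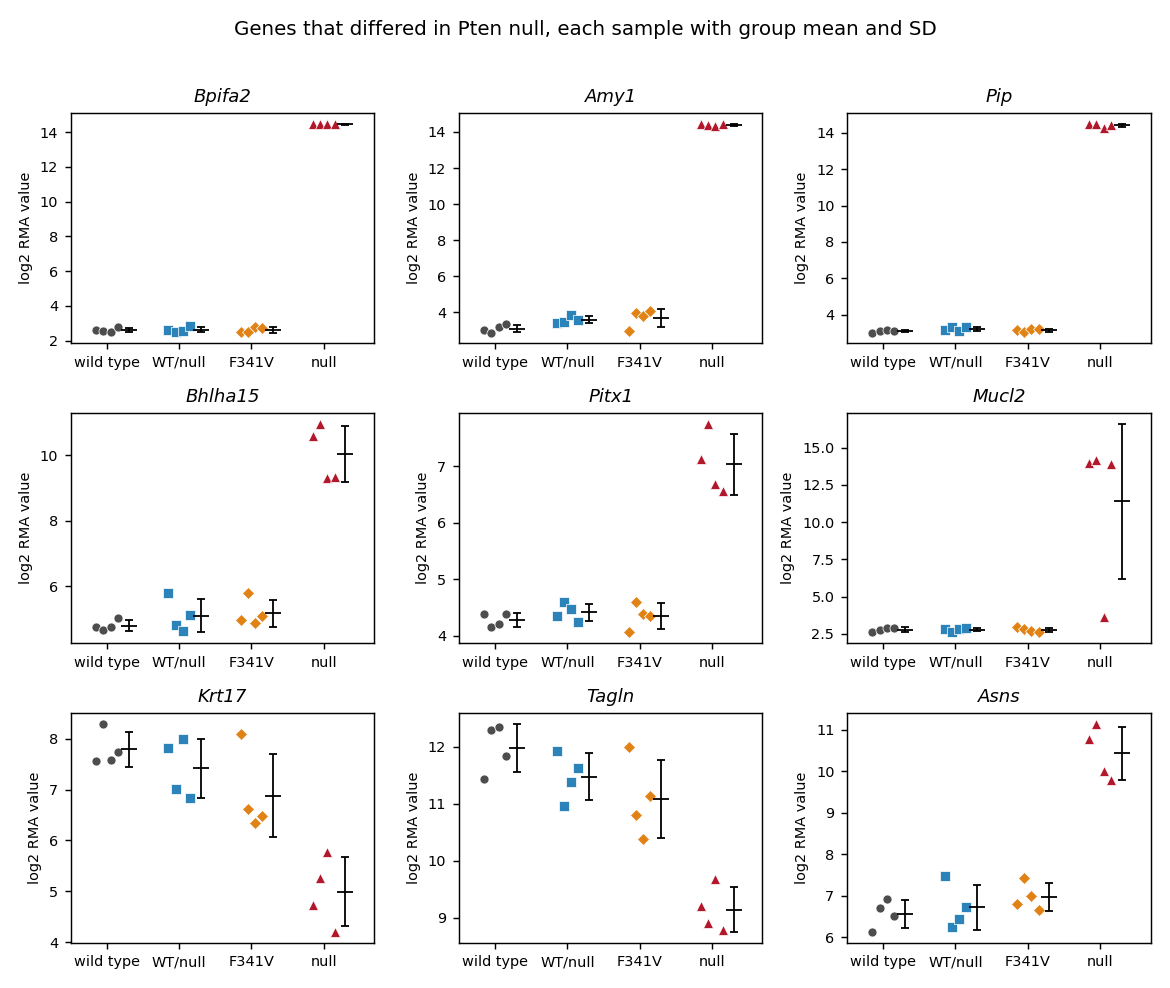
Each panel shows the log2 RMA value (vertical axis) of a gene in the 16 samples by group, with the group mean and SD at the right of each group. Bpifa2, Amy1, Pip, Bhlha15, Pitx1 and Asns lie higher and Krt17 and Tagln lower in all 4 Pten null samples than in all others, with group differences from wild type of the same sign in every scaling tried, and Mucl2 lies at 3.60 in Pten null replicate 3 and at 13.93 or above in the other 3.

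In all, limma found 4488 of 13645 genes changed between Pten null and wild type, 1306 of them higher and 3182 lower, and 1032 changed over 2-fold (326 higher, 706 lower). The split was 1590 higher and 2416 lower after quantile normalization, and 303 higher and 8793 lower with spike-in scaling. In 4326 genes (31.7%) the samples of the groups did not overlap, against the 2.86% that chance gives. The count was 2921 without the wild-type samples of generation 4 and 1683 with Pten null replicates 1 and 2 both left out. Salivary transcripts were high in every Pten null sample. In each comparison with Pten null, changes of genes and lists may therefore come in part from salivary cells in the samples. Such a part could not be told apart from effects of Pten loss in mammary cells.

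Markers of basal and myoepithelial cells, the contractile outer layer of the mammary duct, fell in Pten null against wild type as a whole: 13 of 13 tested members fell, also adjusted over the list alone, with a median of -2.37 log2. The list averaged 7.47 ± 0.43 log2 in Pten null and 9.86 ± 0.49 in wild type (SD, n = 4). Smooth muscle genes were among them, Tagln at -2.83 ± 0.32 (SE), Cnn1 at -2.84 and Actg2 at -3.52, with the basal keratin Krt17 at -2.80. The fall held with each scaling. The camera test gave an adjusted p of 1.13e-07 for it, or adjusted p = 0.989 with an estimated correlation, and fry gave an adjusted p of 0.000698. Of 15 tested genes of ATF4 and amino acid supply 7 rose and 0 fell (7 and 0 adjusted over the list alone), among them Asns, asparagine synthetase (3.87 ± 0.31, SE), Chac1 (1.83) and Phgdh, the first enzyme of serine synthesis (1.86). Their median was 0.36 log2 but turned to -0.14 with spike-in scaling, where 3 rose and 2 fell. It lay 0.47 above the median of all genes with both scalings, since spike-in scaling shifts all genes of an array alike. Camera gave an adjusted p of 0.0028 (adjusted p = 0.989 with an estimated correlation) and fry 0.00766.

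DNA replication and E2F targets, which act as cells enter S phase, fell in 15 of 21 tested members in Pten null, with 0 higher (18 lower and 1 higher adjusted over the list alone), for example Rfc4 (-1.30), Gins2 (-1.23) and Mcm3 (-1.22). The median was -1.04 log2 (camera adjusted p = 0.0028, or adjusted p = 0.989 with an estimated correlation). With spike-in scaling camera no longer called the list (adjusted p = 0.114), although shifting whole arrays leaves its distance from other genes as it was. Without Pten null replicates 1 and 2 the calls of Rfc4, Gins2 and Mcm3 ended (-1.12, -0.998 and -0.78 log2, adjusted p = 0.0951, 0.0642 and 0.0584). Mitosis genes gave 1 rise and 4 falls among 21 (1 and 14 adjusted over the list alone), with a median of -1.65 and an adjusted p of 0.0227 by camera (adjusted p = 0.989 with an estimated correlation). That call ended without Pten null replicate 1 (0.0623), Pten null replicate 2 (0.0521), wild-type replicate 2 (0.10) or wild-type replicate 3 (0.0975), with spike-in scaling (0.653), and with the 50th percentile filter (0.210). Immediate early and dissociation stress genes, which respond within minutes to stimuli and to tissue handling, fell in 9 of 19 members with 0 higher (9 and 0 adjusted over the list alone), as in Egr3 (-2.27), Myc (-1.37) and Fosb (-1.15). Their camera adjusted p of 0.0103 (adjusted p = 0.989 with an estimated correlation) became 0.114 with spike-in scaling and 0.166 without Pten null replicates 1 and 2. Of 18 cytosolic ribosomal protein genes 9 fell and 0 rose (10 and 0 adjusted over the list alone), as in Rpl14 (-1.29) and Rpl10a (-0.45). Camera gave 0.0093 (adjusted p = 0.989 with an estimated correlation), which became 0.102 with backcross generation as a covariate and 0.107 without the wild-type samples of generation 4, where Rpl10a no longer passed either (-0.39 log2 in both, 0.0673 and 0.0645). Leaving out Pten null replicates 1 and 2 also ended the call of Rpl10a (-0.42, 0.0851).

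Milk and alveolar genes were higher in Pten null against wild type with a median of 1.48 log2, and 2 of 11 tested members rose with 0 lower (2 and 0 adjusted over the list alone). These were Glycam1 (3.58 ± 1.12, SE), a secreted milk mucin, and Csn3, kappa-casein (2.19 ± 0.70). The camera adjusted p was 0.0093 (adjusted p = 0.989 with an estimated correlation) and the fry value 0.167. The gene calls were lost when a sample was left out, with differences of 3.07 to 3.58 for Glycam1 and of 1.53 to 2.15 for Csn3. The lowest difference of each came without wild-type replicate 1, and fewer samples are part of the cause of the larger p. Glycam1 ended without Pten null replicate 1 (adjusted p = 0.0511), Pten null replicate 2 (0.0557), wild-type replicate 1 (0.0656) or wild-type replicate 3 (0.0732), and Csn3 without Pten null replicate 1 (0.0591), Pten null replicate 3 (0.0585), wild-type replicate 1 (0.0764) or wild-type replicate 2 (0.0627), or with the mean of its probe sets (1.54 log2, 0.102). With Pten null replicates 1 and 2 both left out, Glycam1 gave 3.54 (0.140) and Csn3 2.35 (0.115). Among 23 genes of oxidative phosphorylation 4 rose, as did Ndufa1 (0.61), and 1, Sdhc, fell (-0.58), or 2 and 1 adjusted over the list alone. With spike-in scaling 0 rose and 8 fell, the list median turned from 0.13 to -0.37, and Ndufa1 stood at 0.11 (adjusted p = 0.535). The camera adjusted p of 0.0093 (adjusted p = 0.989 with an estimated correlation) became 0.0609 with array weights, 0.114 with spike-in scaling, 0.123 without Pten null replicates 1 and 2, and 0.0877 without wild-type replicate 1. B and plasma cell markers had 1 rise in 11, Jchain, the joining chain of secreted antibodies (2.11, adjusted p = 0.0145, or 1.72 and 0.0538 without wild-type replicate 2), also adjusted over the list alone. Their median was 0.49, or -0.01 with spike-in scaling, with a camera adjusted p of 0.0182 (adjusted p = 0.989 with an estimated correlation) that ended without Pten null replicate 3 (0.0877), wild-type replicate 2 (0.0905) or wild-type replicate 3 (0.0950).

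PI3K pathway components, the route that the Pten protein restrains, gave 1 rise and 9 falls in 23 tested members in Pten null against wild type (1 and 11 adjusted over the list alone). Igf1r, the receptor of insulin-like growth factors, fell by 1.21 (SE 0.11), Pik3ip1, an inhibitor of PI3K, by 1.38 and the transcription factor gene Foxo1 by 0.61. The list did not differ from other genes by camera (adjusted p = 0.0930), while fry gave 0.00213 for a fall on balance. FoxO targets gave 2 rises and 4 falls in 16 (2 and 4 adjusted over the list alone), as in Fbxo32, a ubiquitin ligase subunit of muscle wasting (-2.73), Ccng2 (-1.07) and Klf15 (1.90), with a camera adjusted p of 0.971.

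The other lists that camera did not call in Pten null against wild type had adjusted p from 0.0669 to 0.971. Pan-luminal epithelium had 1 rise in 14 and hormone-sensing luminal cells 1 in 9, each with 0 adjusted over the list alone. Fibroblasts had 1 rise and 4 falls in 13 (1 and 5 adjusted over the list alone), and adipocytes 1 fall in 7 (0 adjusted over the list alone). Cholesterol synthesis gave 3 falls in 17, fatty acid synthesis 2 rises and 3 falls in 13, glycolysis and hypoxia 1 and 2 in 18, p53 targets 1 and 2 in 15, NF-kB and secreted inflammatory factors 2 and 3 in 18, and MHC class II 1 fall in 6, with the same counts adjusted over the list alone. The unfolded protein response gave 2 rises and 4 falls in 15 (4 and 4 adjusted over the list alone), and the circadian clock 2 and 2 in 15 (1 and 2 adjusted over the list alone). By limma 0 members passed, also adjusted over the list alone, among 10 luminal progenitor genes (1 at an unadjusted p under 0.05), 11 endothelium genes (0), 14 macrophage and myeloid genes (0), 11 T and NK cell genes (1), 18 interferon response genes (2) and 1 tested red blood cell gene (0, as in every other comparison), and fry called none of these lists that it tested (adjusted p 0.597 to 0.986).

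**Figure D4:**
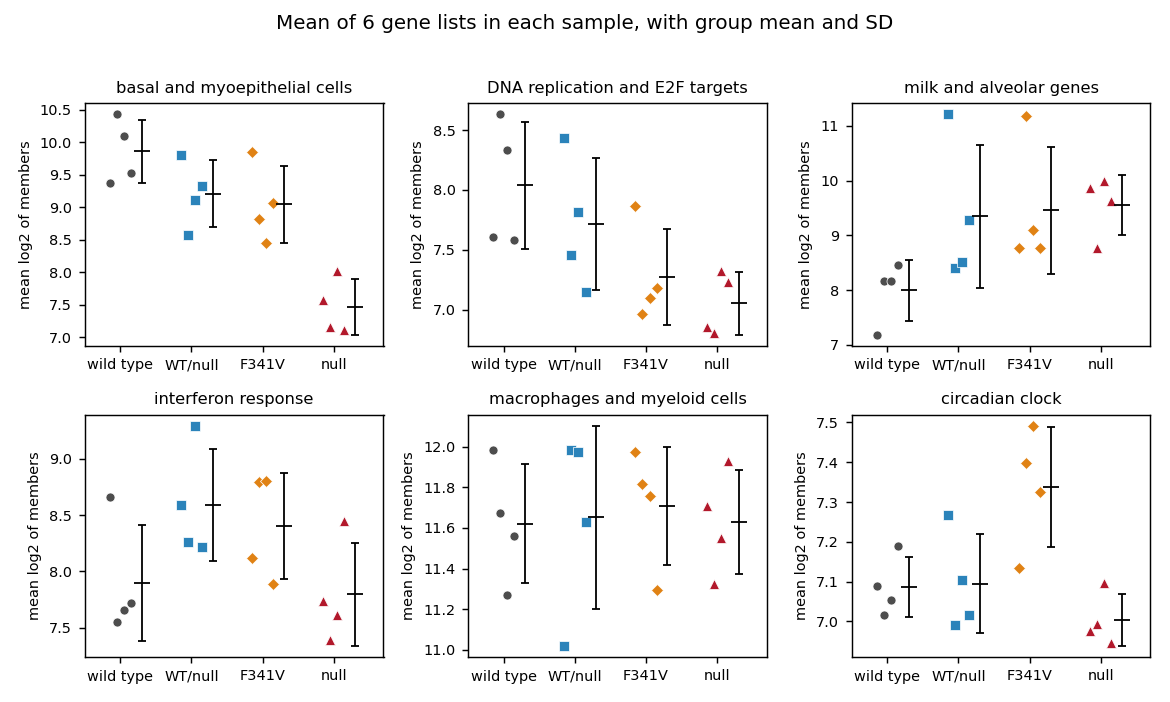
Each panel shows the mean log2 value of the tested members of a gene list (vertical axis) in the 16 samples by group, with the group mean and SD at the right of each group. Basal and myoepithelial markers average 9.86 in wild type, 9.20 in Pten WT/null, 9.04 in Pten F341V and 7.47 in Pten null, and the median differences between these groups keep their signs with spike-in, median and quantile scaling, while macrophage markers lie between 11.62 and 11.71 in every group as deposited.

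The comparison of Pten WT/null with wild type asks what loss of a single allele changed. Lipo3, a lipase family member that neighbours Pten on its chromosome, had the smallest p, at 7.58 ± 0.43 log2 in Pten WT/null and 5.41 ± 0.70 in wild type (SD, n = 4), but its 4.52-fold difference did not pass (adjusted p = 0.0789). It did pass without Pten WT/null replicate 1 (0.0442), without wild-type replicate 1 (0.0248), with spike-in scaling (0.0456) and with array weights (0.0029). The next genes were Fam89a (-0.73 log2), Thoc2l (-0.61), Ppp1r3e, a regulator of glycogen synthesis (1.01), and Ang, the ribonuclease angiogenin (3.74), with adjusted p of 0.851 to 0.994. Ang varied most, at 7.25 ± 2.31 in wild type, and passed without wild-type replicate 2 (adjusted p = 0.00193). Array weights also brought Fam89a (0.0123), Thoc2l (0.0466) and Ang (0.0485) past the threshold.

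By limma 0 of 13645 genes changed between Pten WT/null and wild type, with 658 at an unadjusted p under 0.05 where chance gives 682. Array weights gave 318 genes (66 higher, 252 lower), and leaving out Pten WT/null replicate 1, wild-type replicate 1 or wild-type replicate 2 gave 1 gene each, as did spike-in scaling and the test of all probe sets. In 319 genes (2.34%) the groups did not overlap, against 2.86% by chance. No list kept its camera call with an estimated correlation in this comparison, fry called 0 lists, and 0 members of any list passed limma, also adjusted over the list alone. Interferon response genes, which act against viruses, were higher by a median of 0.78 (camera adjusted p = 8.28e-08, or adjusted p = 0.769 with an estimated correlation), with 16 of 18 higher and 9 at an unadjusted p under 0.05, such as Irf7 (1.17 ± 0.44, SE) and Usp18 (1.04 ± 0.41). Basal and myoepithelial markers were lower in 13 of 13 members by a median of -0.54 (8.28e-08, or adjusted p = 0.769 with an estimated correlation), with 4 at an unadjusted p under 0.05, among them Trp63, a transcription factor of basal cells (-1.18), Actg2 (-1.20) and the basal keratin Krt5 (-0.99). These 3 passed with array weights (adjusted p = 0.0466 each). Without Pten WT/null replicate 2 the median of the basal list was -0.29 (camera adjusted p = 0.00013). Mitosis genes were lower in 21 of 21 members (median -0.77, camera 1.53e-06, or adjusted p = 0.777 with an estimated correlation, 0 at an unadjusted p under 0.05). The mitosis median was -0.41 without wild-type replicate 2 (camera adjusted p = 0.00257) and -1.27 without Pten WT/null replicate 1 (4.98e-09). B and plasma cell markers were higher in 11 of 11 (median 0.64, 0.000265, or adjusted p = 0.777 with an estimated correlation, 1 at an unadjusted p under 0.05). Their median was 0.37 without wild-type replicate 2 (camera adjusted p = 0.0210) and 1.04 without Pten WT/null replicate 1 (6.87e-07).

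Further camera calls in Pten WT/null against wild type ended when a sample was left out. Milk and alveolar genes were higher in 11 of 11 members (median 1.08, 7.5e-06, or adjusted p = 0.769 with an estimated correlation, 4 at an unadjusted p under 0.05). It gave 0.0614 without Pten WT/null replicate 1, 0.152 with array weights and 0.325 without Pten WT/null replicates 1 and 4. DNA replication and E2F targets were lower (median -0.31, 0.000265, or adjusted p = 0.777 with an estimated correlation, 0 at an unadjusted p under 0.05). It gave 0.145 without Pten WT/null replicate 4 and 0.186 without wild-type replicate 2. Fibroblast markers were lower (median -0.47, 0.00207, or adjusted p = 0.777 with an estimated correlation, 2 at an unadjusted p under 0.05). It gave 0.251 without Pten WT/null replicate 1, 0.154 without wild-type replicate 4, 0.567 with array weights, 0.220 with generation as a covariate and 0.271 without the wild-type samples of generation 4. Without Pten WT/null replicates 1 and 4 the fibroblast median was -0.17 and camera's direction turned (adjusted p = 0.985). Ribosomal protein genes were slightly lower (median -0.07, 0.00695, or adjusted p = 0.777 with an estimated correlation, 0 at an unadjusted p under 0.05). It gave 0.125 without Pten WT/null replicate 2, 0.0925 without Pten WT/null replicate 3, 0.145 without wild-type replicate 3, 0.0588 without wild-type replicate 4, 0.795 with generation as a covariate and 0.805 without the wild-type samples of generation 4.

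The comparison of Pten F341V with wild type asks what the F341V allele beside a loxP allele changed. By limma 5 genes rose and 0 fell. Lipo3 was 6.70-fold higher (8.15 ± 0.50 against 5.41 ± 0.70 log2, SD, n = 4, adjusted p = 0.00495) and Slc16a12, a transporter gene that also neighbours Pten, 5.74-fold higher (6.97 ± 0.83 against 4.45 ± 0.56, adjusted p = 0.0324). H2bc22, a histone H2B gene, rose by 0.93 (adjusted p = 0.0290), Unc13b, which acts in vesicle release, by 0.73 (0.0290) and Hagh, an enzyme of methylglyoxal removal, by 0.62 (0.0246), with all 4 Pten F341V samples above all 4 wild-type samples in each of the 5. A dim second probe set of Unc13b gave -0.06, and others of Hagh gave 0.41 and 0.32 without passing. With the mean of its probe sets Unc13b no longer passed (0.33, adjusted p = 0.308). All 5 genes also rose in Pten null against the same wild-type samples. Sharing controls gave a mean of 1.92 of 5 in simulated draws without any Pten F341V change, and 6 of 100 draws gave 5, so this overlap does not set the genes apart from chance. With the wild-type samples split between the comparisons, 0, 0, 0, 1, 3 and 8 genes rose in Pten F341V, of which 0, 0, 0, 1, 2 and 6 also rose in Pten null. Both tests were added after the overlap had been seen. In Pten null Lipo3 rose by 2.72 (adjusted p = 4.71e-05) and Slc16a12 by 1.90 (0.00231). The values of Lipo3 and Slc16a12 outside this comparison are given because of what was seen here.

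Whether these genes passed depended on samples and settings. Lipo3 missed the threshold only when the fit held no other groups (adjusted p = 0.302) or lacked the wild-type samples of generation 4 (0.0860). Those settings ended the other 4 as well, as did generation as a covariate (Slc16a12, H2bc22 and Unc13b 0.0934 each, Hagh 0.151). The covariate took the differences to 2.91, 1.06, 0.79 and 0.60 in that order, so these calls ended without smaller differences except in Hagh. The count was 25 without Pten F341V replicate 1, 1 without Pten F341V replicate 2, Pten F341V replicate 3 or wild-type replicate 1, 2 without wild-type replicate 2 or wild-type replicate 4, 3 with the 50th percentile filter, 754 with array weights (322 higher, 432 lower), 2 with the replicate block, 2 with spike-in scaling and 8 over all probe sets. Without Pten F341V replicates 2 and 3 in turn the adjusted p became 0.191 and 0.169 for Slc16a12, 0.120 and 0.123 for H2bc22, 0.155 and 0.137 for Unc13b, and 0.0717 and 0.0895 for Hagh. Without wild-type replicates 1, 2 and 4 in turn it became 0.0929, 0.152 and 0.0914 for Slc16a12, 0.0860, 0.0804 and 0.0621 for H2bc22, 0.0541, 0.0804 and 0.0621 for Unc13b, and 0.0559, 0.0716 and 0.0621 for Hagh, and without Pten F341V replicate 4 it was 0.0538 for H2bc22 and 0.0642 for Unc13b. Where these left-out samples ended a call, the difference was 2.28 to 2.51 for Slc16a12, 0.81 to 0.96 for H2bc22, 0.64 to 0.77 for Unc13b and 0.55 to 0.65 for Hagh. At an unadjusted p under 0.05 there were 1394 genes where chance gives 682, and 692 genes (5.07%) did not overlap between the groups, against 2.86% by chance.

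**Figure D5:**
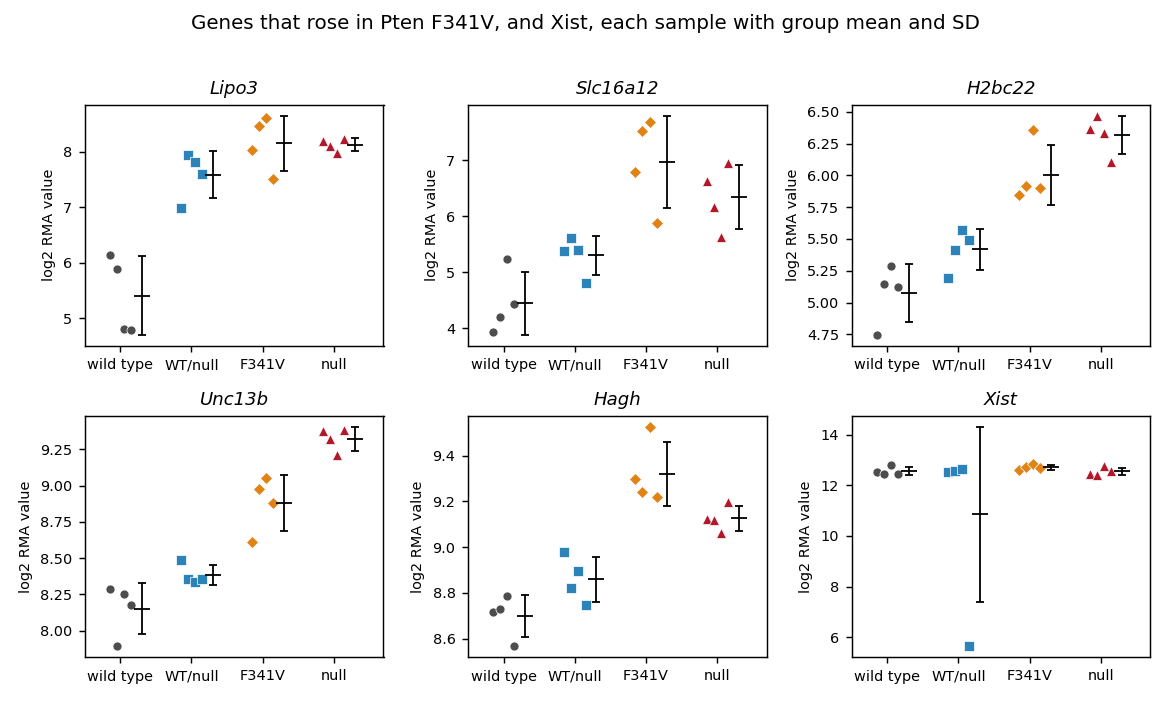
Each panel shows the log2 RMA value (vertical axis) of a gene in the 16 samples by group, with the group mean and SD at the right of each group. Lipo3, Slc16a12, H2bc22, Unc13b and Hagh lie higher in all 4 Pten F341V samples than in all 4 wild-type samples, with group differences of the same sign in spike-in, median and quantile scaling, and Xist lies at 5.66 in Pten WT/null replicate 4 and at 12.42 or above in the other 15.

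By gene lists, DNA replication and E2F targets were lower in 21 of 21 members in Pten F341V against wild type, with a median of -0.69 (camera adjusted p = 9.82e-13, or adjusted p = 0.566 with an estimated correlation). By limma 0 members fell over all genes and 11 fell adjusted over the list alone, with 14 at an unadjusted p under 0.05, such as Mcm2 (-0.88 ± 0.26, SE), Mcm3 (-0.82) and Rrm2 (-1.38), which supply the replication fork. Mitosis genes were lower in 21 of 21 (median -1.17, 6.37e-09, or adjusted p = 0.648 with an estimated correlation, 2 at an unadjusted p under 0.05). Basal and myoepithelial markers were lower in 13 of 13 (median -0.75, 2.9e-08, or adjusted p = 0.566 with an estimated correlation), with 1 fall adjusted over the list alone and 7 at an unadjusted p under 0.05, such as Actg2 (-1.59) and Cnn1 (-1.02). Milk and alveolar genes were higher in 11 of 11 (median 1.34, 0.000118, or adjusted p = 0.566 with an estimated correlation, 4 at an unadjusted p under 0.05), such as Csn3 (2.09) and Btn1a1, a protein of milk fat globules (2.57). Without Pten F341V replicate 2, whose list mean of 11.19 lay above the 8.77 to 9.10 of the other 3, the milk median was 0.56 (adjusted p = 0.0197). With array weights Mcm2, Mcm3, Rrm2, Actg2, Cnn1, Csn3, Btn1a1 and Rtp4 passed, with adjusted p from 0.0171 to 0.0408. No camera call of this comparison held with an estimated correlation and fry called 0 lists.

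The remaining camera calls in Pten F341V against wild type ended under some settings. Pan-luminal markers were higher in 14 of 14 members (median 0.76, 0.000563, or adjusted p = 0.744 with an estimated correlation, 1 at an unadjusted p under 0.05). It gave 0.146 without wild-type replicate 1. Interferon response genes were higher in 17 of 18 (median 0.46, 0.000899, or adjusted p = 0.744 with an estimated correlation, 1 at an unadjusted p under 0.05), as in Rtp4 (0.87). It gave 0.157 with generation as a covariate and 0.149 without the wild-type samples of generation 4. Cholesterol synthesis genes were lower in 13 of 17 (median -0.11, 0.00841, or adjusted p = 0.566 with an estimated correlation, 1 fall adjusted over the list alone, 5 at an unadjusted p under 0.05). It gave 0.0529 without wild-type replicate 4, 0.0540 with generation as a covariate and 0.0627 with the 50th percentile filter. Circadian clock genes were higher in 13 of 15 (median 0.22, 0.0216, or adjusted p = 0.516 with an estimated correlation, 4 at an unadjusted p under 0.05). It gave 0.0776 without Pten F341V replicate 3 and 0.0808 with the 50th percentile filter. Fibroblast markers were higher in 12 of 13 (median 0.39, 0.0216, or adjusted p = 0.744 with an estimated correlation, 2 at an unadjusted p under 0.05). It gave 0.172, 0.0514 and 0.164 without Pten F341V replicates 1, 2 and 4 in turn, 0.0993 without wild-type replicate 2 and 0.0808 with the 50th percentile filter.

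The comparison of Pten F341V with Pten WT/null asks how the F341V allele differed from a lost allele. Clock genes were higher in Pten F341V in 13 of 15 members, with a median of 0.28 log2, as in Nr1d2, a repressor of the clock's feedback loop (0.59 ± 0.17, SE), Per3 (0.58 ± 0.19) and Cry2 (0.34 ± 0.13). The list averaged 7.34 ± 0.15 in Pten F341V and 7.09 ± 0.12 in Pten WT/null (SD, n = 4), and the higher level held with each scaling. Over all comparisons, this was the only camera call that held with an estimated correlation (adjusted p = 0.000427, or adjusted p = 0.0404 with an estimated correlation), while fry gave 0.0553. These values are adjusted over the lists of this comparison only, not over all the comparisons from which the call stands out. The clock median fell to 0.15 without Pten WT/null replicate 4 (camera adjusted p = 0.0013 with the preset correlation). By limma 0 clock genes passed over all genes and 1 rose adjusted over the list alone, with 5 at an unadjusted p under 0.05. Fibroblast markers were higher in 13 of 13 members (median 1.06, 2.24e-09, or adjusted p = 0.238 with an estimated correlation), with 0 passing over all genes, 5 adjusted over the list alone and 8 at an unadjusted p under 0.05, as in the growth factor receptor gene Pdgfra (1.51) and the matrix proteoglycan genes Dcn (1.06) and Lum (1.61).

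By limma 0 of 13645 genes changed between Pten F341V and Pten WT/null, with 639 at an unadjusted p under 0.05 where chance gives 682. The 5 smallest p belonged to Ccr1 (-2.08), Hagh (0.46), Mmp9, a matrix protease (-2.56), Fkbp8 (-0.34) and Ldlrad3 (-0.50), each with an adjusted p of 0.479. Leaving out Pten WT/null replicate 1 gave 3 genes, Mmp9 among them (adjusted p = 0.0207), array weights gave 47 (19 higher, 28 lower), and Ccr1 passed with the mean of its probe sets (0.0251), with array weights (0.0265) and over all probe sets, where its second probe set gave -2.37 (0.0085). Array weights also brought Hagh (0.0236), Mmp9 (0.00335), Fkbp8 (0.0341), Nr1d2 (0.0341) and Slc16a12 (0.0341) past the threshold. Slc16a12 differed by 1.67 (adjusted p = 0.614) and Lipo3 by 0.57 (0.996). In 386 genes (2.83%) the groups did not overlap, against 2.86% by chance. DNA replication and E2F targets were lower in 21 of 21 members (median -0.40, 1.79e-07, or adjusted p = 0.940 with an estimated correlation, 2 at an unadjusted p under 0.05). Their median was -0.17 without Pten WT/null replicate 1 (camera adjusted p = 0.0291) and -0.62 without Pten F341V replicate 1 (2.72e-11).

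Smaller camera calls in Pten F341V against Pten WT/null each ended without certain samples. FoxO targets were higher (median 0.18, 0.0235, or adjusted p = 0.238 with an estimated correlation). It gave 0.0603 without Pten F341V replicate 3 and 0.133 without Pten WT/null replicate 2. Pan-luminal markers were higher (median 0.38, 0.0270, or adjusted p = 0.940 with an estimated correlation). It gave 0.0612 and 0.436 without Pten F341V replicates 3 and 4, 0.220 and 0.644 without Pten WT/null replicates 2 and 3, and 0.0533 with the 50th percentile filter. B and plasma cell markers were lower (median -0.48, 0.0270, or adjusted p = 0.940 with an estimated correlation). It gave 0.0540, 0.0612 and 0.0602 without Pten F341V replicates 1, 3 and 4, 0.183, 0.191 and 0.277 without Pten WT/null replicates 2, 3 and 4, and 0.0813 with the 50th percentile filter. MHC class II genes were lower (median -0.49, 0.0339, or adjusted p = 0.940 with an estimated correlation). It gave 0.396 without Pten F341V replicate 3, 0.218, 0.246 and 0.206 without Pten WT/null replicates 2, 3 and 4, and 0.0506 after quantile normalization. Mitosis genes were lower (median -0.37, 0.0339, or adjusted p = 0.940 with an estimated correlation), gave 0.206 and 0.841 without Pten F341V replicates 2 and 3 and 0.116 without Pten WT/null replicate 3, and turned to a median of 0.09 without Pten WT/null replicate 1 (adjusted p = 0.730). The mitosis call also ended with no filter (0.0506), the 50th percentile filter (0.0813), the mean of probe sets (0.0845), array weights (0.277), quantile normalization (0.0507), spike-in scaling (0.260) and without Pten WT/null replicates 1 and 4 (0.619).

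The comparison of Pten null with Pten WT/null asks what loss of the remaining allele changed. The same salivary genes rose, Bpifa2 (14.45 ± 0.02 against 2.63 ± 0.16 log2, SD, n = 4, adjusted p = 1.25e-19), Cst10 (11.50 log2), Pip (11.17), Smr3a (11.05), Dnase1 (11.03), Amy1 (10.81), Prpmp5 (10.59), Chia1 (10.32), Dcpp1 (9.38) and Car6 (9.14). All but Car6 averaged under 4.30 log2 in Pten WT/null, and Car6 read under it in 2 of the 4 samples, so the sizes again say little beyond a large rise. Among the falls were genes of myeloid and immune cells, Ccr1 (-4.01), Mmp9 (-3.34), Slfn4 (-2.97) and the lectin gene Cd209d (-2.91), beside Wif1 (-3.20), the chemokine gene Cxcl14 (-2.89), Adamts20 (-2.88), Tenm2 (-2.84) and Grik3, a glutamate receptor gene (-2.88), whose second probe set gave -0.09. Nupl1 fell by 4.01 on its brightest probe set, against -0.48, -0.28 and -0.16 on the others, and dim probe sets of Tenm2 gave 0.21 and 0.42. The macrophage and myeloid list as a whole had 0 of 14 members past the limma threshold, with 0 at an unadjusted p under 0.05. Slfn4 no longer passed without Pten null replicates 1 and 2 (-2.83, adjusted p = 0.0576). Adamts20 and Grik3 averaged under 4.30 log2 in Pten null, so the sizes of their falls are uncertain.

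Limma found 4023 genes changed between Pten null and Pten WT/null, 1151 higher and 2872 lower, with 707 over 2-fold (280 higher, 427 lower). The split was 1347 and 1997 after quantile normalization and 271 and 8724 with spike-in scaling, which took the median of all genes from -0.14 to -0.62. The count was 2602 without Pten null replicate 2 and 1139 without Pten null replicates 1 and 2. In 3629 genes (26.6%) the groups did not overlap, against 2.86% by chance. Basal and myoepithelial markers fell in 11 of 13 members (12 adjusted over the list alone) by a median of -1.76, as in Cnn1 (-2.65 ± 0.34, SE), Tagln (-2.33), Krt17 (-2.43) and Oxtr, the oxytocin receptor gene (-2.80), with a camera adjusted p of 6.86e-05 (adjusted p = 0.998 with an estimated correlation) and 0.00461 by fry. In ATF4 and amino acid supply 6 of 15 genes rose and 1 fell (7 and 1 adjusted over the list alone), as in Asns (3.71), Phgdh (2.12) and Chac1 (1.93), with a median of 0.42, or -0.06 with spike-in scaling (camera 0.000268, or adjusted p = 0.968 with an estimated correlation). Oxidative phosphorylation gave 5 rises and 1 fall in 23 (5 and 1 adjusted over the list alone), as in Ndufa1 (0.51, or 0.03 with spike-in scaling and an adjusted p of 0.846), with a median of 0.20, or -0.28 with spike-in scaling (camera 0.000268, or adjusted p = 0.998 with an estimated correlation).

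Immediate early and dissociation stress genes fell in 8 of 19 members in Pten null against Pten WT/null (10 adjusted over the list alone), as in Fosb (-1.35), by a median of -0.47 (camera 0.0415, or adjusted p = 0.998 with an estimated correlation). That list call ended without Pten null replicate 1 (0.0608), Pten null replicate 2 (0.151), Pten WT/null replicate 2 (0.0626) or Pten WT/null replicate 4 (0.109), with median centring (0.0544), spike-in scaling (0.188) or the 50th percentile filter (0.192), and without Pten WT/null replicates 1 and 4 (0.0714) or Pten null replicates 1 and 2 (0.356). PI3K pathway components fell in 7 of 23 members (8 adjusted over the list alone, camera 0.279, fry 0.00461), and FoxO targets gave 3 rises and 4 falls in 16 (also adjusted over the list alone, camera 0.931).

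The comparison of Pten null with Pten F341V asks how loss of both alleles differed from the F341V allele. Bpifa2 was higher in Pten null (14.45 ± 0.02 against 2.61 ± 0.15 log2, SD, n = 4, adjusted p = 1.02e-19), as were Cst10 (11.66 log2), Dnase1 (11.26), Pip (11.24), Smr3a (11.02), Amy1 (10.70), Prpmp5 (10.64), Chia1 (10.33), Dcpp1 (9.37) and Mucl2, a mucin-like gene (8.63), which was low in Pten null replicate 3 and no longer passed without Pten null replicates 1 and 2 (5.99, adjusted p = 0.0714). All 10 averaged under 4.30 log2 in Pten F341V, so here too the sizes say little beyond a large rise. The falls were Wif1 (-3.20), Tenm2 (-3.00), Cxcl14 (-2.82), Oxtr (-2.67), Grik3 (-2.65), Bex1 (-2.58), Maob, a monoamine oxidase (-2.38), Pdk4, a kinase that restrains pyruvate oxidation (-2.33), and Cyp1b1, a cytochrome P450 (-2.32). Nupl1 fell by 3.90 on its brightest probe set only. Dimmer probe sets of Oxtr (-0.21), Grik3 (0.04), Cyp1b1 (-0.06) and Tenm2 (0.22 and 0.37) did not pass. The call of Pdk4 ended without Pten null replicate 1 (-2.08, adjusted p = 0.0546), Pten F341V replicate 2 (-2.04, 0.0510) or Pten F341V replicate 3 (-2.03, 0.0514). Without Pten null replicates 1 and 2 together, the calls of Oxtr (-2.36, 0.0541), Bex1 (-2.43, 0.0692), Maob (-1.91, 0.0768), Pdk4 (-1.91, 0.190) and Cyp1b1 (-2.10, 0.155) ended. Grik3 averaged under 4.30 log2 in Pten null, so the size of its fall is uncertain.

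Limma found 3906 genes changed between Pten null and Pten F341V, 1094 higher and 2812 lower, with 646 over 2-fold (233 higher, 413 lower). The split was 1235 and 1632 after quantile normalization and 257 and 7174 with spike-in scaling, which took the median of all genes from -0.16 to -0.55. The count was 2562 without Pten null replicate 1, 2227 without Pten null replicate 2 and 725 without both. In 4059 genes (29.7%) the groups did not overlap, against 2.86% by chance. Basal and myoepithelial markers fell in 11 of 13 members (12 adjusted over the list alone) by a median of -1.69, as in Tagln (-1.93 ± 0.32, SE), Cnn1 (-1.82), Oxtr (-2.67) and Myh11, smooth muscle myosin (-1.64), with a camera adjusted p of 0.000112 (adjusted p = 0.977 with an estimated correlation). In ATF4 and amino acid supply 7 of 15 genes rose and 0 fell (8 and 0 adjusted over the list alone), as in Asns (3.47), Phgdh (2.45) and Aldh18a1, an enzyme of proline synthesis (1.60), with a median of 0.37, or -0.02 with spike-in scaling (camera 5.89e-05, or adjusted p = 0.539 with an estimated correlation). Without Pten null replicates 1 and 2 the calls of Myh11 (-1.58, 0.0657) and Aldh18a1 (0.9998, 0.0893) ended.

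Oxidative phosphorylation gave 3 rises and 1 fall in 23 genes in Pten null against Pten F341V (also adjusted over the list alone) with a median of 0.16, or -0.22 with spike-in scaling (camera 0.00124, or adjusted p = 0.977 with an estimated correlation). Immediate early and dissociation stress genes fell in 10 of 19 members (12 adjusted over the list alone) by a median of -0.53 (camera 0.0138, or adjusted p = 0.977 with an estimated correlation), as in Egr3 (-1.64), Myc (-1.05) and Fosb (-1.05). Spike-in scaling (0.0753), the 50th percentile filter (0.0713) and the absence of Pten null replicates 1 and 2 (0.197) ended that list call, and without those replicates Egr3 (-1.16, 0.0715), Myc (-0.82, 0.0931) and Fosb (-0.66, 0.0799) missed the threshold too. Fibroblast markers fell in 7 of 13 members (11 adjusted over the list alone) by a median of -1.40 (camera 0.0487, or adjusted p = 0.977 with an estimated correlation). That call ended without Pten null replicate 1 (0.0738), Pten null replicate 4 (0.0527), Pten F341V replicate 1 (0.0845), Pten F341V replicate 2 (0.0641) or Pten F341V replicate 4 (0.0998), with median centring (0.0526), the 50th percentile filter (0.247), spike-in scaling (0.119), the replicate block (0.0574), and without Pten null replicates 1 and 2 (0.142). PI3K pathway components fell in 8 of 23 members (8 adjusted over the list alone, camera 0.0757, fry 0.00364), with Igf1r at -0.89. FoxO targets gave 1 rise and 6 falls in 16 (also adjusted over the list alone, camera 0.736).

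Pten WT/null was also compared with the midpoint of wild type and Pten null, which is where it would lie if each lost allele had the same effect on a log2 scale. The genes with the smallest p were Pip (-5.52 log2, SE 0.07), Bpifa2 (-5.89), Cst10 (-5.70), Dnase1 (-5.48) and 2310057J18Rik (-5.05), which lay below the midpoint because Pten WT/null and wild type were both low. All 5 averaged under 4.30 log2 in both groups, so the distances say little beyond their direction. By limma 284 genes lay off the midpoint, 175 above and 109 below, with 80 by over 2-fold (15 above, 65 below). The split was 337 above and 114 below with median centring, 84 and 112 after quantile normalization, and 497 and 69 with spike-in scaling, which took the median of all genes from 0.07 to 0.30. Interferon response genes lay above the midpoint by a median of 0.71 (camera 0.000475), with 0 over all genes, 8 adjusted over the list alone and 12 at an unadjusted p under 0.05. ATF4 and amino acid supply lay below it by a median of -0.27 (0.000409), with 1 below over all genes and 4 adjusted over the list alone, and oxidative phosphorylation by -0.13 (0.000285), with 0 passing limma and 3 at an unadjusted p under 0.05. Each of the 3 gave adjusted p = 0.957 with an estimated correlation, and fry called 0 lists.

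The count off the midpoint moved with single samples. It was 712, 147, 103 and 112 without Pten WT/null replicates 1, 2, 3 and 4 in turn, 182 and 165 without wild-type replicates 2 and 3, and 168, 490 and 436 without Pten null replicates 1, 3 and 4.

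Across the 13645 genes, which are not independent replicates, changes from the shared wild-type samples were compared in 3 pairs. Changes in Pten null and Pten F341V had a Pearson's r of 0.508 and a Spearman's rho of 0.454, against a mean r of 0.423 in draws that shared only controls, and 36 of 100 draws were as large. For Pten null and Pten WT/null r was 0.446 and rho 0.374 (simulated mean r 0.514, 68 of 100 as large), and for Pten F341V and Pten WT/null r was 0.735 and rho 0.616 (0.508, 16 of 100). The covariance was 0.120 against a simulated 0.0237, 0.0879 against 0.0289 and 0.0635 against 0.0270 in the same order. With the wild-type samples split so that no control was shared, r over 6 splits ranged from 0.213 to 0.474, from 0.162 to 0.393 and from 0.0851 to 0.573. The mean over splits was 0.352, 0.268 and 0.356. Unchanged groups split the same way had a 95th percentile of 0.524, 0.502 and 0.550, with 15, 18 and 16 of 100 draws as large as the mean. For Pten F341V with Pten WT/null, similarity was therefore not shown. For the pairs with Pten null these draws of r cannot decide, since they gave no group changes of its own. The many changes of Pten null widen its spread, which lowers r for the same covariance. All 3 covariances lay above their simulated means, but draws as large were not counted for them.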

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

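The tests of scaling, of genes switched on by Pten loss, of dilution, of chance placement beside Pten and of a male animal were chosen only after the results they measure had been seen, and so were the lists of salivary genes. Among 488 groups of 4 samples, 28 held a sample set far apart from the other 3, where chance alone picks out about 1 in 20 groups, or 24.4 here. Gene list means gave 11 of 112 such groups (5.6 by chance), array measures 1 of 16 (0.8) and named genes 16 of 360 (18).

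In Pten null, genes of salivary secretions rose to the top of the array's range, with the secretory list at 10.86 ± 0.23 log2 against 3.67 ± 0.12 in wild type, and basal markers fell. Scaling does not account for the rises, since spike-in scaling, which moved them most, takes only 0.50 log2 from each and leaves the lowest of the 10 largest at 8.79. Basal markers fell further than markers of T and NK cells, myeloid cells and endothelium together (difference -0.60 ± 0.43 in Pten null, 1.65 ± 0.74 in wild type, exact permutation p = 0.0286, the smallest possible). They also fell further than those of fibroblasts (-0.61 ± 0.42 and 1.10 ± 0.77) and adipocytes (-0.64 ± 0.54 and 1.47 ± 0.67), which themselves lay lower by 0.69 and 0.29. This argues against an even dilution of all mammary RNA by salivary RNA as the whole cause of the lower basal markers. Dilution of mammary epithelium alone stays open, since the test took these other cells to come from the mammary gland only, which was not checked. Myeloid markers differed by 0.005 log2. Salivary gland cells collected with the mammary gland stay open, since a second list of salivary genes had a median of 0.46 log2 with 8 of 14 higher, and since the CDH1 sort would keep salivary epithelium, which also carries CDH1. Pten loss switching these genes on in mammary cells stays open too, as the lowest Pten null sample lay 7.04 log2 above wild type and every null sample carried both the genotype and the transcripts. Salivary cells and Pten loss as explanations of the rises cannot be told apart with the samples at hand. Both may contribute to the counts of changed genes in Pten null and to the genes and lists named there.

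Lipo3 and Slc16a12 neighbour Pten on its chromosome and were higher in Pten F341V and Pten null than in wild type. Backcross generation as the whole cause is argued against, since the wild-type generations differed by at most 44.0% of the Pten F341V difference (1.21 of 2.74 log2 for Lipo3) and by -0.77 log2, the other direction, for Slc16a12, and against wild-type samples of generation 3 alone Lipo3 went from 2.74 to 2.14 and Slc16a12 from 2.52 to 2.91, each with an adjusted p of 0.0860, calls that ended with fewer samples, while in Pten null the differences of 2.12 and 2.28 still passed (0.000913 and 0.0055). DNA around the engineered alleles from another strain may carry these differences, but the test could not decide. In Pten F341V 7 of the 40 neighbours had an unadjusted p under 0.05 (17.5% against 10.2% of all genes), all higher. A share of 0.114 of windows elsewhere held as many. In Pten WT/null 6 neighbours did (15% against 4.82% of all genes), all higher. Of these, 3 were the clustered interferon genes Ifit3, Ifit1bl1 and Ifit1. Their list had a median of 0.78, but its camera call did not hold with an estimated correlation and fry did not call it. In Pten null 22 did (55.0% against 43.4% of all genes), of which only 8 were higher. Chance placement stays open, since the 0.00836% of draws of 5 genes that put 2 or more among the 40 neighbours restates what was first noticed, and so does an effect of the altered Pten alleles on their neighbours, which was not tested.

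Xist, the RNA that silences an X chromosome, stood at 5.66 log2 in Pten WT/null replicate 4 and between 12.51 and 12.65 in the other 3 of its group, and its other probe sets were low there as well (3.21 and 2.92). A male animal is argued against, since no Y-linked probe set lay more than 0.464 log2 above the mean of the other 15 samples. Low RNA quality or input stays open, since Xist was picked for standing furthest apart, so that the 0.00733% of tested genes that deviated as much is Xist alone and the share expected without this cause was wrongly set. The sample had the highest 3'-to-5' differences of its group (Actb 1.75 against 1.14 to 1.32, Gapdh 1.24 against 0.67 to 0.90) and poly-A spike controls at 7.92 log2 against 6.29 to 7.24 in the other 15, though both differences were higher still in Pten F341V replicate 3 (Gapdh 1.60), with Xist at 12.84. Genes that escape X inactivation averaged -0.365 log2 against the rest of the group, while the other 15 samples ranged from -0.133 to 0.282 in the same measure. A single X chromosome in place of 2, in the animal or in the cells sampled, would give such a difference. The evidence is weak, since the group held Pten WT/null replicate 1 at 10.29. By level the sample averaged 9.80 log2, close to the 9.85 of Pten null replicate 2, where Xist stood at 12.42.

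Other gene list means set apart were pan-luminal markers at 10.17 in Pten null replicate 3 (9.31 to 9.46 in the other 3), milk and alveolar genes at 11.19 in Pten F341V replicate 2 (8.77 to 9.10) and fibroblast markers at 8.20 in Pten F341V replicate 3 (9.41 to 9.63). In Pten WT/null replicate 1, T and NK cell markers stood at 5.30 (6.46 to 6.55), B and plasma cell markers at 6.35 (7.83 to 8.05), ATF4 and amino acid supply at 7.95 (7.38 to 7.43) and MHC class II at 8.87 (10.57 to 10.71). Glycolysis and hypoxia stood at 8.13 in Pten null replicate 3 (7.77 to 7.81) and the interferon response at 8.66 in wild-type replicate 1 (7.55 to 7.72). The p53 targets stood at 8.83 in wild-type replicate 3 (8.97 to 8.98) and at 9.10 in Pten WT/null replicate 4 (8.87 to 8.89). The 20 brightest probe sets held 3.64% of the signal in Pten WT/null replicate 1 (3.87% to 3.92%).

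Single genes set apart in Pten null were Mucl2 at 3.60 in replicate 3 (13.93 to 14.14), Dcn at 11.31 (10.11 to 10.27), Fam89a at 4.54 (4.72 to 4.75) and Pip at 14.27 (14.43 to 14.45) in the same sample, Nr1d2 at 10.52 in replicate 1 (10.27 to 10.31), Rspo1 at 3.48 in replicate 2 (4.31 to 4.46) and Usp18 at 7.81 in replicate 4 (6.71 to 6.82). In Pten F341V they were Adamts20 at 6.73 (3.68 to 4.19), Krt17 at 8.09 (6.35 to 6.62) and Mcm2 at 8.03 (7.50 to 7.54) in replicate 1, Ppp1r3e at 6.55 in replicate 2 (5.89 to 5.93), and Egf at 3.98 (3.54 to 3.60) and H2bc22 at 6.36 (5.85 to 5.91) in replicate 3. Dcn stood at 11.76 in wild-type replicate 4 (10.45 to 10.62) and Unc13b at 8.49 in Pten WT/null replicate 1 (8.34 to 8.36).

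Probe sets without a gene name in the annotation, which entered no comparison above, also changed between Pten null and wild type, 1403 of 9160 of them (986 higher, 417 lower). In the other comparisons with Pten null the number was 1378 against Pten WT/null and 1537 against Pten F341V.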

How the results depend on the processing

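Spike-in scaling and leaving out Pten WT/null replicates 1 and 4 or Pten null replicates 1 and 2 together were chosen only after the data had been seen. Over all alternatives and named genes, 2338 values of passing genes kept their direction and their side of the threshold and 79 did not, while 636 values of genes that had not passed stayed so and 28 passed. For list calls 776 stayed, 172 were lost and 2 reversed, and for lists not called 2549 stayed, 191 were called and 6 reversed.

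Where samples or genes were left out, fewer of them are part of the cause of a lower count, and for every other change below the cause was not tested. Changed genes in Pten null against wild type numbered 9096 with spike-in scaling (3485 shared with the 4488), 2921 without wild-type samples of generation 4 and 1683 without Pten null replicates 1 and 2 (1656 shared), and 3207 to 4385 with 1 sample left out. Against Pten WT/null they numbered 8995 with spike-in scaling, 1139 without Pten null replicates 1 and 2, and from 2602 (without Pten null replicate 2) to 4327. Against Pten F341V they numbered 7431, 725, and from 2227 (without Pten null replicate 2, with 2562 without replicate 1) to 3933.

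Pten WT/null against wild type moved from 0 by limma (658 at an unadjusted p under 0.05) to 318 with array weights, and to 1 with spike-in scaling, over all probe sets, and without Pten WT/null replicate 1, wild-type replicate 1 or wild-type replicate 2. Pten F341V against wild type moved from 5 to 3 with the 50th percentile filter, 0 with only the groups compared in the fit, 754 with array weights, 2 with spike-in scaling, 1 with generation as a covariate, 0 without wild-type samples of generation 4 (limma, with 1394 at an unadjusted p under 0.05 in all samples) and 8 over all probe sets. Leaving out 1 sample gave from 1 to 25, as listed above. Pten F341V against Pten WT/null moved from 0 by limma (639 at an unadjusted p under 0.05) to 1 with the mean of probe sets, 47 with array weights, 1 over all probe sets and 3 without Pten WT/null replicate 1.

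Genes off the midpoint moved from 284 to 164 with only the groups compared in the fit, 3097 with array weights, 451 with median centring, 566 with spike-in scaling, 144 with generation as a covariate, 101 without wild-type samples of generation 4, 154 without Pten WT/null replicates 1 and 4, 128 without Pten null replicates 1 and 2, and 852 over all probe sets. Leaving out 1 sample gave from 103 to 712, as listed above.

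Directions that reversed were those of lists. Against wild type, fatty acid synthesis in Pten WT/null went from 0.04 log2 to -0.36 with array weights, -0.35 without Pten WT/null replicates 1 and 4, and -0.33 without replicate 1 alone, with up to 0.237 over the alternatives (without replicate 2). Fibroblast markers went from -0.47 to -0.17, where camera's direction turned, without replicates 1 and 4. In Pten F341V against Pten WT/null, macrophage markers went from 0.07 to -0.26 without those replicates and to -0.16 without replicate 1, with up to 0.177 over the alternatives (without Pten WT/null replicate 2). Without replicate 1, T and NK cell markers went from -0.04 to -0.30, where only camera's direction against other genes turned (at most 0.0734, without Pten WT/null replicate 3) and mitosis genes from -0.37 to 0.0851 (at least -0.780, without Pten F341V replicate 1).

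Leaving out 1 sample took r from 0.508 to between 0.450 and 0.573 for Pten null with Pten F341V, from 0.446 to between 0.372 and 0.524 for Pten null with Pten WT/null, and from 0.735 to between 0.589 and 0.817 for Pten F341V with Pten WT/null. Camera with an estimated correlation kept 1 of 43 list calls, and fry kept 12.

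Replicate numbers did not pair the samples, since 4 of 24 pairs with the same number correlated above 0.1 and 9 below -0.1, and 2 of 16 samples correlated best with their own number. With the replicate block the counts were 3981, 3464 and 3257 for Pten null against wild type, Pten WT/null and Pten F341V, 2 for Pten F341V against wild type, and 138 off the midpoint. The arrays' signal over background limits dim genes, and without the filter on them 4827 genes changed between Pten null and wild type.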

Other observations

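The divisions of samples reported here were planned, and no test was added after their results were seen. For Pten null against wild type the divisions argue against chance, since 1 of 35, the real one, gave as many as its 4488 genes. The highest other gave 1. That share of 1 in 35 is the smallest that 4 against 4 samples allow, so the divisions alone do not exclude chance. The same holds for Pten null against Pten WT/null (1 of 35, 4023 genes, highest other 1254) and against Pten F341V (1 of 35, 3906 genes, highest other 0 by limma, where the real groups had 5641 at an unadjusted p under 0.05). The 1254 came from exchanging Pten WT/null replicate 1 with Pten null replicate 4.

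For Pten F341V against wild type chance cannot be excluded, since 2 of 35 divisions gave as many as its 5 genes and exchanging Pten F341V replicate 1 with wild-type replicate 4 gave 172. A count of 0 is reached by every division, so for the next comparisons the test says nothing. For Pten WT/null against wild type 35 of 35 gave at least its 0 genes by limma (658 at an unadjusted p under 0.05), and exchanging Pten WT/null replicate 1 with wild-type replicate 1 gave 1635. For Pten F341V against Pten WT/null 35 of 35 gave at least 0 by limma (639 at an unadjusted p under 0.05), with 28 when the replicates numbered 3 were exchanged. The 1635 and the 172 point to a structure of the samples other than their groups. Off the midpoint, 2 of 100 regroupings gave as many as 284, with 635 as the highest other. These regroupings ask whether all 3 groups were alike, which the change in Pten null already rules out, so they say nothing about where Pten WT/null lay against the midpoint.

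In Pten null against wild type, median differences in 4 equal bins of the genes' mean level were 0.10, 0.03, -0.19 and -0.15 log2 from the dimmest to the brightest. Lists of exocrine pancreas genes (0 of 5 passed by limma, 1 at an unadjusted p under 0.05, median 0.11) and of genes that escape X inactivation (0 of 4 passed by limma, 1 at an unadjusted p under 0.05, median -0.27) were added after the values had been seen.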
